A study of Manihot esculenta with 44 samples.

How the data were processed

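RNA was measured in leaves of cassava (Manihot esculenta), variety KU50, grown from stem cuttings in 1 field in Hanoi and 1 field in Bac Kan, Vietnam, in 2019. The series contrasts a general field, where the plants did not flower, with a mountainous area, where they flowered. There were 44 libraries in 11 groups of 4, with 4 dates in Hanoi (24 May, 13 July, 7 August, 10 October) and 7 in Bac Kan (31 May, 29 June, 26 July, 15 August, 11 September, 5 October, 30 October). Per the labels, total RNA was turned into cDNA and adaptor-ligated libraries were amplified by 14 cycles of PCR and sequenced as pairs. Site and date were taken from the sample titles, which the descriptions repeat. The characteristics gave another date for 40 of the 44 samples and another site for 16. Their dates ran through the same sequence of 11 again and again, with 33 samples repeating the date 11 samples before, so they were not used. In the values, the closest library of 43 of the 44 belonged to the group that the title names. Each group sat in a table of its own, so this does not test whether the site and date given for a table are right.

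The authors aligned the reads with TopHat2 (version not given). The deposited values are FPKM, fragments scaled for transcript length and for library size, in 11 tables, 1 per group, each with 41491 transcripts. The quantifier, the genome build, the annotation release and any further normalization were not given in the sources used here. Every comparison between groups therefore crosses tables. The 30 October table of Bac Kan held 1 further column, equal in all 41491 transcripts to the column of that name in the 5 October table, and this copy was not used. The columns name a group but no replicate number, so a library number below is only the place of a column in its table.

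FPKM were summed over the transcripts of each of 34120 gene IDs, of which 5253 had more than 1 transcript, and rescaled in each library to a total of 1000000. Genes at 1 or more in at least 4 of the 44 libraries were tested, which left 23405 genes, 11 of them with noncoding RNA IDs. Values were analysed as log2(x + 1). The deposited annotation gave an Arabidopsis best hit for 28526 IDs, among them 21850 of the genes tested, and a description for 25633. Gene names below are those of the best hit and do not separate close copies of a gene. The reference table of gene symbols held none of the cassava IDs, so no chromosome positions were assigned.

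A single limma fit (version 3.58.1, R 4.3.3) covered the 11 groups, with empirical Bayes variances that followed a trend with the level. Each Hanoi date was compared with the nearest Bac Kan date, each Bac Kan date used once. The pairs lay 7 days apart in late May, 13 in July, 8 in August and 5 in October, when Bac Kan was sampled first. The other comparisons were the mean of the 4 site differences, the change of the site difference between pairs (an F test with 3 degrees of freedom), the change over dates within Bac Kan (6 degrees of freedom) and within Hanoi (3), and the last against the first date at each site. A Benjamini-Hochberg adjusted p under 0.05 was a call, and all tests were two-sided.

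The 19 gene lists were fixed before the data were examined and matched by the Arabidopsis best hit. They were the florigen and TFL1 family, floral integrators and meristem identity, floral repressors, photoperiod pathway and photoreceptors, circadian clock, floral organ identity, gibberellin, cold and dehydration, heat shock, phenylpropanoid and flavonoid, photosynthesis, starch, sugar and trehalose, sugar starvation and senescence, salicylate and immune defence, jasmonate, abscisic acid, nitrogen and phosphate status, cell proliferation and meristem, and secondary wall and xylem. The floral organ, cell proliferation and secondary wall lists stood for flower, young or woody tissue in a sample. Each list was tested in 7 contrasts with camera, with an inter-gene correlation preset at 0.01 and again with an estimated one, and with fry, adjusted over the 19 lists within a contrast. Camera sets a list against all other genes, and fry asks whether its members moved 1 way on balance.

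The genes named were chosen by a rule fixed before the data were examined. It took, per contrast, the 6 largest rises and 6 largest falls among calls with a name, the 4 libraries of one group all above those of the other, and a mean of 5 or more in the higher group. For the mean of the pairs that separation was asked in at least 3 pairs. It also took up to 4 called members of each list, the 6 smallest p of each F test, and in every case the florigen family and the homologues of SOC1, AP1, FUL, LFY, CO, GI, FKF1, LHY and TOC1. From these, genes whose call held under the alternatives that were run were preferred in the text.

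The tables used here hold no read counts, so the absolute depth is unknown and no counting error can be given. A relative depth was estimated from the spacing of low values over 2426 genes, and 818 of 946 pairs of libraries lay within 0.1 log2 units of the fitted depths. Of 3212 genes with a median of 50 or more, 50 were listed at 0 in at least 1 library, with 242 such values, so a 0 is not always a low level. Genes with such values are given below as ranges over libraries, and fold changes against a group listed at 0 in all 4 libraries, which depend on the pseudocount, are left out of the findings. Ranges of the site difference that rest on such a group are marked where they are given. The procedure was tested on simulated data with the October pair: of genes shifted by 1, 2 and 4 log2 units, 30.9, 78.8 and 98.5 percent were called, and 5 of 23205 unshifted genes were. A shifted list was called there and 0 of the others, but the simulated genes were drawn independently. In the data the estimated correlation between members was 0.241 for photosynthesis and 0.193 for heat shock. The simulation therefore cannot show false list calls that come from correlated members. Its shares of shifted genes called do not give the sensitivity in the data either. It shifted 68, 66 and 66 genes, where 5657 were called in the real October pair.

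The alternatives were the deposited FPKM without rescaling, median-ratio scaling, pseudocounts of 0.1 and 5, no filter and a filter of 5, variances without a trend, a fit of only the groups compared, calls with at least 1 log2 unit, an adjusted p under 0.01, each library left out in turn, the 11 date means as samples, all dates of each site, and Bac Kan 29 June in place of 26 July. Chosen after seeing the data were the mean without the late May pair, the mean without the October pair, and the most abundant transcript of each gene in place of the sum. Other splits of the libraries were drawn with seed 11, at most 100 per result. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.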

Results

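Transcript levels were measured in leaves of the cassava variety KU50 at a general field in Hanoi, where plants did not flower, and at a mountainous site in Bac Kan, where they flowered. There were 16 libraries from 4 Hanoi dates and 28 from 7 Bac Kan dates, 4 per date. Deposited FPKM summed to between 664145 and 804362 per library, and 18275 to 19777 genes stood at 1 or more after rescaling. Read totals are unknown. The relative depth, estimated from the values, ran from 0.802 to 1.649, with 1.19 ± 0.261 (SD, n = 16) in Hanoi and 1.04 ± 0.196 (SD, n = 28) in Bac Kan. Levels below are FPKM rescaled to a total of 1000000, as mean ± SD of 4 libraries. Where a library was listed at 0, the range over the 4 libraries is given instead. Fold changes are log2 ± SE, and p values are limma's, adjusted over the 23405 genes tested. A positive site difference means a higher level in Bac Kan. Unless stated otherwise, all 4 libraries of one group lay above all 4 of the other for each named gene that was called in a date pair.

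Libraries of a group resembled each other more than those of other groups, with a median correlation across genes of 0.927 within groups and 0.885 between them. The 4 Hanoi libraries of 24 May were the least alike, with a mean correlation of 0.877 with their own group. The first 2 components of the values held 15 and 8.69 percent of the variance. Library composition also differed between the sites. The share of noncoding RNA IDs was 0.757 to 0.979 percent in Bac Kan on 26 July against 0.242 to 0.326 in Hanoi on 13 July. It was 0.362 to 0.686 against 0.182 to 0.279 percent in the August pair and 0.468 to 0.776 against 0.138 to 0.230 in the October pair, while the late May groups overlapped. The late May groups differed in the share of the 10 most abundant genes. That share was 13.2 to 15.3 percent in Hanoi on 24 May against 8.67 to 9.17 in Bac Kan on 31 May. In Hanoi it averaged 8.08 percent on 10 October. The relative depth was 1.334 to 1.649 in Hanoi on 10 October against 0.84 to 0.994 in Bac Kan on 5 October, and overlapped in the other pairs. Whether RNA quality or library preparation differed was not tested, and the site differences below carry this limit. Each site was a single field, and the paired dates lay 5 to 13 days apart. The labels do not say whether the libraries of a date came from separate plants or at which hour leaves were taken. Site is therefore not separable from field, day and hour, and p values measure differences against the spread between the samples of a date.

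**Figure D1:**
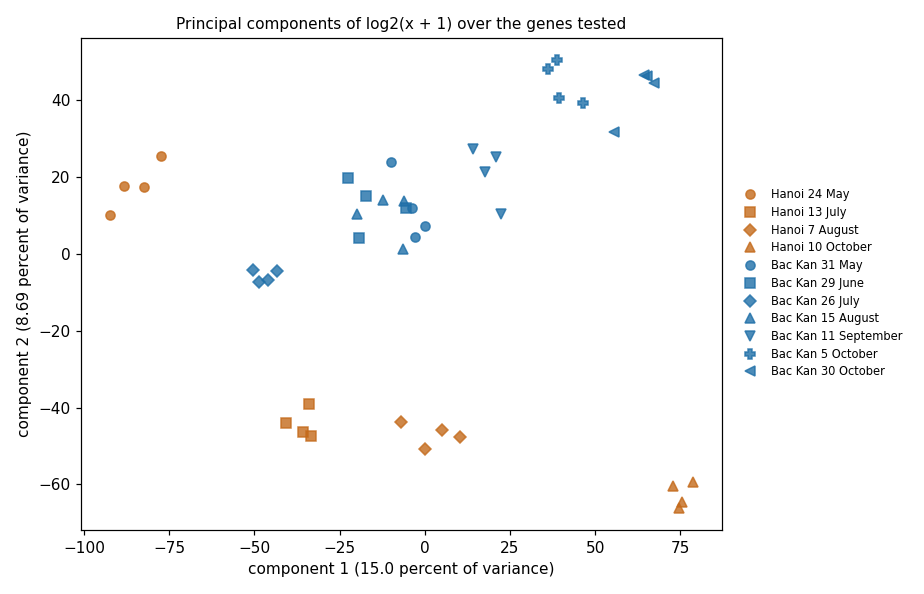
Principal components of log2(x + 1) over the genes tested, 1 point per library, with Hanoi in orange and Bac Kan in blue and a marker per date. The axes hold 15 and 8.69 percent of the variance, and the 4 libraries of a date lie near each other.

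The central question was which leaf transcripts differed between the flowering and the non-flowering site, and the florigen genes come first. FT encodes the mobile florigen made in leaves. The FT homologue MANES_13G000800 lay between 0 and 1.21 in the 16 Hanoi libraries. In Bac Kan it was listed at 0 on 31 May, spanned 0 to 13.2 on 29 June and 0 to 15.5 on 26 July, and reached 6.92 ± 2.52 on 15 August and 18 ± 7.33 on 11 September. It stood at 8.61 ± 6.39 on 5 October and 5.9 ± 3.07 on 30 October. The other FT homologue, MANES_12G001600, was listed at 0 in all 16 Hanoi libraries and in the 12 Bac Kan libraries up to 26 July. It then spanned 0 to 14.6 on 15 August, 0 to 31 on 11 September, 1.41 to 11 on 5 October and 0 to 9.6 on 30 October.

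MANES_13G000800 was called higher in Bac Kan in August (2.38 ± 0.67, adjusted p = 0.0116), in October, where libraries of the sites overlapped (adjusted p = 0.00329), and in the mean of the pairs (adjusted p = 0.000187). In July it was 1.7 with adjusted p = 0.11, and without library 3 of Bac Kan 26 July the difference was 2.49 with adjusted p = 0.014. MANES_12G001600 was called in October (adjusted p = 0.00281) and in the mean (adjusted p = 0.012), but not in August (adjusted p = 0.0684), and without the October pair the mean was not called (adjusted p = 0.299). Over the 7 Bac Kan dates both genes changed, with adjusted p = 0.000178 for MANES_13G000800 and adjusted p = 0.000408 for MANES_12G001600. The change of the site difference between pairs had adjusted p = 0.0863 for the former and adjusted p = 0.0421 for the latter. The call of MANES_12G001600 in that test was lost with a pseudocount of 5 (adjusted p = 0.139), without a filter, with median-ratio scaling, with the deposited FPKM and without several single libraries. The calls of both genes in the mean were lost when the 11 date means were the samples.

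**Figure D2:**
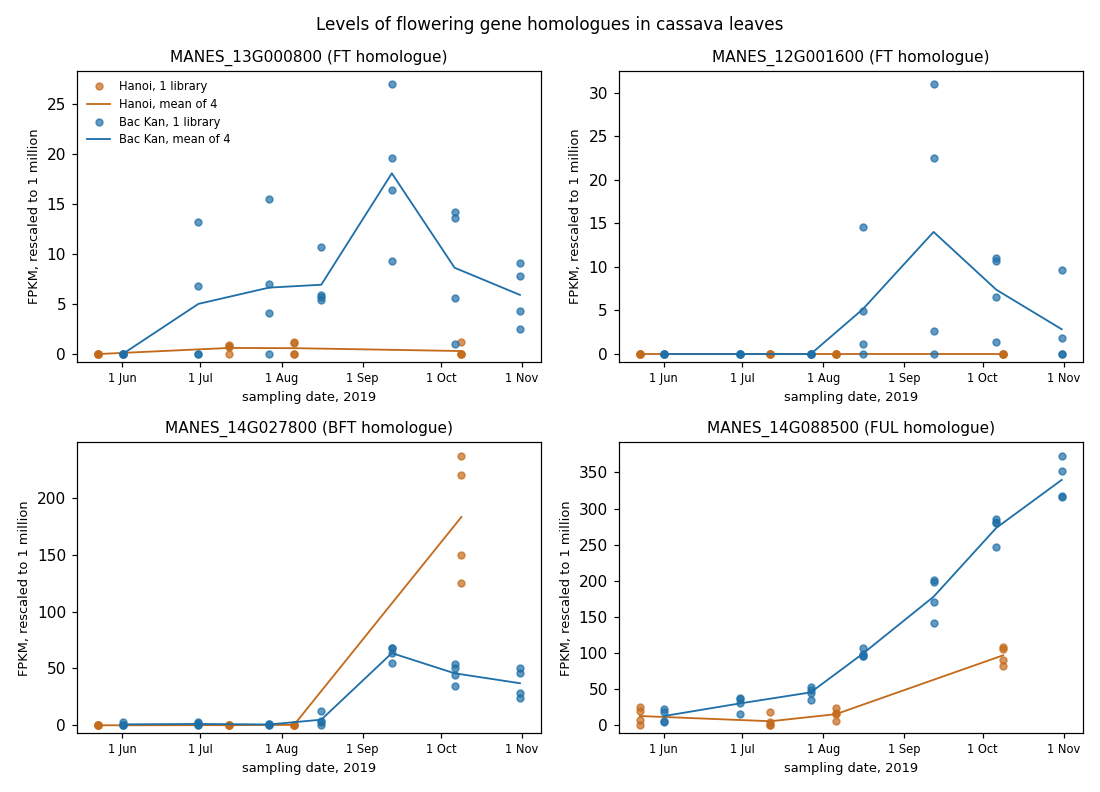
Levels of 4 flowering gene homologues by sampling date in 2019, as FPKM rescaled to a total of 1000000 on linear axes, with 1 point per library and lines through the means of 4. In Hanoi, MANES_12G001600 was listed at 0 in all 16 libraries and MANES_13G000800 did not exceed 1.21, and the BFT homologue MANES_14G027800 reached 183 ± 54 (SD, n = 4) on 10 October.

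BFT, a relative of FT that delays flowering in Arabidopsis, showed another course. The BFT homologue MANES_14G027800 did not exceed 0.637 in Hanoi up to 7 August and reached 183 ± 54 on 10 October. In Bac Kan it spanned 0 to 2.83 up to 26 July and 0 to 12.7 on 15 August, and stood at 63.4 ± 6.31 on 11 September, 45.7 ± 8.25 on 5 October and 37 ± 13.1 on 30 October. It was lower in Bac Kan in October (-1.95, adjusted p = 0.00155), a call lost with a pseudocount of 0.1 (adjusted p = 0.189). In August it was higher (1.57, adjusted p = 0.0161) although libraries overlapped, which ended without library 1 of Bac Kan 15 August (0.99, adjusted p = 0.15) and without library 1 of Hanoi 7 August, with a pseudocount of 0.1, and with only the groups compared. The mean of the pairs was 0.21 with adjusted p = 0.578. The other family members stayed below the test filter: 3 TFL1 homologues, 2 ATC homologues and MANES_06G008200 (MFT) were listed at 0 throughout, and MANES_16G019600 (MFT) did not exceed 0.536.

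FUL and SOC1 encode transcription factors that act downstream of florigen. The FUL homologue MANES_14G088500 climbed in Bac Kan from 12.9 ± 8.87 on 31 May to 45.6 ± 8.2 on 26 July, 99.3 ± 5.18 on 15 August and 340 ± 28.1 on 30 October. In Hanoi it spanned 0 to 25.4 on 24 May and 0 to 18.4 on 13 July, with 2 of 4 libraries at 0 on the latter date, averaged 15.4 ± 7.36 on 7 August and reached 96.9 ± 12.4 on 10 October, against 273 ± 18 in Bac Kan 5 days earlier. It was called in July (adjusted p = 0.000121, a call lost with only the groups compared), in August (2.76, adjusted p = 0.003, a call lost with a pseudocount of 0.1) and in the mean (2.16, adjusted p = 3.61e-06), and not in October (1.49, adjusted p = 0.103). The October libraries were nonetheless fully apart, at 246 to 286 in Bac Kan and 82.3 to 108 in Hanoi. That p uses a spread shared over the 11 groups, among them Hanoi dates with libraries at 0. The interaction was called (adjusted p = 0.0214), but not with only the groups compared, a pseudocount of 0.1 or without several single libraries. The call in the mean was lost when the 11 date means were the samples. The FUL homologue MANES_06G081800 rose from the first to the last date at both sites, by 4.70 in Bac Kan and 3.76 in Hanoi, and was called at no pair (p of 0.217 or more). The third, MANES_02G059300, was higher in Bac Kan in late May (1.43, adjusted p = 1.58e-05), and its mean difference was 0.00. It stood at 30.2 ± 8.66 against 48.1 ± 10.4 in August and 43.8 ± 4.27 against 60 ± 6.9 in October without a call, and the mean without the late May pair was called lower (-0.48, adjusted p = 0.00918).

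The SOC1 homologue MANES_05G041900 rose in Hanoi by 3.0, to 239 ± 22.8 on 10 October, and in Bac Kan by 1.75, to 138 ± 15 on 30 October. In October it was lower in Bac Kan (-1.18, adjusted p = 6.22e-05). Both of these Bac Kan results depended on how transcripts were added up: with only the most abundant transcript the October p was 0.454 and the change in Bac Kan was -1.55 without a call (adjusted p = 0.492). The other SOC1 homologue, MANES_01G263500, was also lower in Bac Kan in October (-0.95, adjusted p = 0.0175), a call lost with only the groups compared and without a single library. Of the meristem identity genes, LFY and 2 of 3 AP1 homologues were listed at low values or 0 in these leaves. LFY homologues reached at most 0.558 (MANES_06G127100) and 1.4 (MANES_14G044200) in any library, and the AP1 homologues MANES_01G025600 and MANES_05G111900 reached 0 and 1.56. The third AP1 homologue, MANES_01G103200, passed the filter, was highest in Bac Kan on 30 October (5.94 ± 2.77), and was called at no pair.

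Among day-length and clock genes, the CO homologue MANES_01G024100 was listed at 0 in Hanoi in late May against 3.33 ± 1.53 in Bac Kan (adjusted p = 0.00196). The GI homologue MANES_18G095000 was higher in Bac Kan in August (0.62, adjusted p = 0.0146) and October (0.69, adjusted p = 0.0037), and lost both calls with only the most abundant transcript. The August call was also lost without any 1 of 3 libraries. LHY, a clock gene that peaks at dawn, had 2 homologues that were lower in Bac Kan in October. MANES_01G239000 stood at 25 ± 5.74 against 94.6 ± 12.6 in Hanoi (-1.89, adjusted p = 1.79e-06), and MANES_05G015600 at 76.1 ± 13.9 against 267 ± 15.8 (-1.81, adjusted p = 2.16e-07). In late May MANES_05G015600 had been higher in Bac Kan, at 45.3 ± 9.45 against 20.1 ± 8.14 (adjusted p = 0.000154). The evening clock gene TOC1 was higher in Bac Kan in October in both homologues, MANES_06G089800 (1.25, adjusted p = 0.000602) and MANES_14G081500 (0.95, adjusted p = 0.00305). MANES_06G089800 was also called higher in late May (0.75, adjusted p = 0.0362), where libraries of the sites overlapped. The FKF1 homologue MANES_15G134900 was called at no pair, with p between 0.305 and 0.952.

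The late May pair asked which transcripts differed at the start of sampling, Bac Kan on 31 May against Hanoi on 24 May. Most called jasmonate, immune and abscisic acid genes were lower in Bac Kan, and most called photosynthesis, photoperiod and flavonoid genes were higher. The abscisic acid, photosynthesis and flavonoid lists lost their call with an estimated correlation. Of the 39 jasmonate genes tested, 18 were lower and 2 higher. JAZ8 (MANES_17G071600), a repressor induced by the wound hormone jasmonate, stood at 0.899 ± 0.876 in Bac Kan and 67 ± 36.1 in Hanoi (-5.05 ± 0.43, adjusted p = 2.8e-11). JAZ2 (MANES_03G042500) was at 2.34 ± 2.05 against 83.2 ± 30.8. OPR3 (MANES_03G039700), an enzyme of jasmonate synthesis, was at 6.49 ± 1.9 against 69.9 ± 36.5 (-3.07 ± 0.34, adjusted p = 5.55e-09). Of 41 immune genes, 15 were lower and 0 higher. Among them WRKY53 (MANES_05G030900) was at 10.5 ± 11.1 against 116 ± 34.5 (-3.97 ± 0.53, adjusted p = 3.06e-07), and WRKY40 (MANES_11G066500) at 3.52 ± 2.55 against 33.4 ± 11.5. Of 46 abscisic acid genes, 15 were lower and 7 higher. RD22 (MANES_06G160100) was at 19.8 ± 7.75 against 218 ± 63.6 (-3.44 ± 0.36, adjusted p = 1.57e-09), and NCED3 (MANES_15G102000), which makes the precursor of abscisic acid, spanned 0 to 3.22 against 32.1 ± 19.6.

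Higher in Bac Kan in late May were 29 of 44 photosynthesis genes, with 2 lower. LHCB2.1 (MANES_01G175600) stood at 1080 ± 277 against 319 ± 103 and LHCB1.4 (MANES_17G066800) at 2961 ± 595 against 1074 ± 288, both antenna proteins. In the photoperiod list, 16 of 30 genes were higher and 0 lower, among them CDF2 (MANES_05G103100) at 41.4 ± 7.58 against 8.51 ± 1.15. The clock gene PRR5 (MANES_05G016200) was at 34.9 ± 6.39 against 9.45 ± 3.77. In the flavonoid list, 16 of 38 were higher and 2 lower. Chalcone synthase (MANES_11G075100), the first enzyme of flavonoid synthesis, was at 165 ± 40.9 against 18.8 ± 5.6 (3.08 ± 0.26, adjusted p = 2.58e-11), and DFR (MANES_18G022300) at 23.5 ± 8.95 against a range of 0 to 1.97. The largest named rise was RL6 (MANES_05G158300), a MYB-like gene, at 225 ± 65.7 against a range of 0 to 13.9. The sugar transporter SWEET17 (MANES_01G120400) was at 57.4 ± 11 against 4.4 ± 0.875 (3.43 ± 0.24, adjusted p = 2.89e-13), and the galactinol synthase GolS1 (MANES_05G012000) at 163 ± 74.3 against 8.69 ± 0.551. The ammonium transporter AMT1.1 (MANES_03G156400) was at 59.8 ± 18.9 against 18 ± 6.89.

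SPL genes promote the adult phase and flowering and are held down by a microRNA. At that date they went both ways, and the list that holds them was not called (adjusted p = 0.49). SPL5 (MANES_03G106900) stood at 40.4 ± 6.78 against 809 ± 178 (-4.28 ± 0.35, adjusted p = 1.19e-11), and SPL3 (MANES_16G029900) spanned 0 to 8.32 against 47.6 ± 15.8, while SPL4 (MANES_13G144400) was higher (1.32, adjusted p = 1.95e-08). Heat shock genes went both ways, 10 higher and 7 lower of 46. HSP21 (MANES_01G042200) was at 241 ± 83 against 6.51 ± 2.35, and HSFA2 (MANES_03G049500), a heat shock regulator, at 10.1 ± 4.83 against 69.8 ± 34. Cold and dehydration genes were 7 higher and 7 lower of 24, with ELIP1 (MANES_15G033100) higher (2.44 ± 0.32, adjusted p = 2.26e-07). Among genes outside the lists, the ubiquitin ligase PUB29 (MANES_02G176900) spanned 0 to 0.414 in Bac Kan against 50 ± 18, MAPKKK19 (MANES_12G103600) was at 1.68 ± 1.43 against 69.2 ± 20.8, and RALFL27 (MANES_01G102300) was listed at 0 against 45.8 ± 38.4.

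In all, 6714 genes were called in late May, 3759 higher and 2955 lower (56 percent higher, or 50.8 with median-ratio scaling), and 20.9 percent of genes had fully separated libraries against 2.86 percent by chance. With only the groups compared, 3458 were called. The list test was passed by photosynthesis (adjusted p = 1.59e-09), jasmonate (adjusted p = 1.46e-08), immune defence (adjusted p = 1.88e-06), photoperiod (adjusted p = 1.05e-05), flavonoid (adjusted p = 0.000928) and abscisic acid (adjusted p = 0.0102). With an estimated correlation the adjusted p was 0.022 for jasmonate and 0.01 for immune defence and for photoperiod, but 0.105 for photosynthesis, 0.087 for flavonoid and 0.185 for abscisic acid. Adjusted over the list alone, 31 photosynthesis, 21 jasmonate, 16 immune, 17 photoperiod, 19 flavonoid and 25 abscisic acid genes passed.

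The July pair asked the same of Bac Kan on 26 July and Hanoi on 13 July. Heat shock genes were higher in Bac Kan, 22 of 46 with 0 lower. HSP90.1 (MANES_06G152800), a chaperone, stood at 170 ± 19.6 against 10.1 ± 5.01 (4.05 ± 0.52, adjusted p = 1.41e-06). HSFA2 (MANES_03G049500) was at 36.5 ± 6.81 against a range of 0 to 0.912, the reverse of late May. The F test over all 4 pairs, which does not single out July and late May, had adjusted p = 9.13e-10 for it. HSP17.6C (MANES_14G148700) was at 44.4 ± 14.1 against a range of 0 to 2.79. Of 24 cold and dehydration genes, 3 were higher and 0 lower, among them the dehydrin COR47 (MANES_05G140400) at 2102 ± 252 against 522 ± 115 (2.03 ± 0.16, adjusted p = 4.29e-11) and ELIP1 (MANES_15G033100) at 336 ± 79.6 against 77.9 ± 21.5. Of 46 abscisic acid genes, 10 were higher and 4 lower. HY5 (MANES_16G120300), a regulator of light responses on the flavonoid list, was at 57.4 ± 6.03 against 13.6 ± 2.41.

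Lower in Bac Kan in July were 11 of 44 photosynthesis genes, with 4 higher. PSBQ2 (MANES_16G017000) was at 1052 ± 132 against 2225 ± 394 (-1.07 ± 0.16, adjusted p = 1.78e-05). Of 39 jasmonate genes, 5 were lower and 2 higher, with the lipoxygenase LOX2 (MANES_10G148800) at 61.4 ± 19.3 against 214 ± 35.3 (-1.82 ± 0.20, adjusted p = 5.48e-08). The germin-like gene GER3 (MANES_11G020100) was at 19.5 ± 5.07 against 522 ± 191, and the wall enzyme XTH9 (MANES_12G076800) at 11.6 ± 6.99 against 211 ± 62.4. MLP423 (MANES_05G089800) was at 22.5 ± 8.4 against 449 ± 234, and the terpene synthase TPS21 (MANES_15G078900) differed by -3.62 ± 0.39. SPL5 (MANES_03G106900) was lower again, at 76.7 ± 9.29 against 214 ± 63.3 (-1.43 ± 0.35, adjusted p = 0.00627). SWEET17 (MANES_01G120400) was higher, at 29.8 ± 6.05 against 9.61 ± 4.81, as was the phosphatase PS2 (MANES_04G138100), a phosphate-status gene, at 183 ± 45 against 37.1 ± 5.73 (2.24 ± 0.22, adjusted p = 6.01e-09).

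In July 2068 genes were called, 1211 higher and 857 lower (58.6 percent higher, or 50.7 with median-ratio scaling), and 12.6 percent of genes had fully separated libraries against 2.86 percent by chance. With only the groups compared 1201 were called, and with Bac Kan 29 June in place of 26 July 3387. The list test was passed by heat shock (adjusted p = 4.84e-16), photosynthesis (adjusted p = 2.88e-05), jasmonate and abscisic acid (each adjusted p = 0.014) and cold (adjusted p = 0.0264). With an estimated correlation heat shock had an adjusted p of 0.047, and the others lost the call, with adjusted p = 0.407 for photosynthesis, 0.414 for jasmonate and 0.339 for abscisic acid and for cold. When adjusted over the list alone, 27 heat shock, 20 photosynthesis, 9 jasmonate, 19 abscisic acid and 7 cold genes passed.

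The August pair set Bac Kan on 15 August, when both FT homologues were present in Bac Kan, against Hanoi on 7 August. Most called photosynthesis, starch, gibberellin and nitrogen genes were higher in Bac Kan, and most called immune genes were lower, but with an estimated correlation each of these lists lost its call. Of 44 photosynthesis genes, 14 were higher and 1 lower, with the aldolase FBA2 (MANES_02G101600) at 598 ± 83.2 against 178 ± 27.8 (1.74 ± 0.16, adjusted p = 6.06e-10) and Rubisco activase (MANES_10G027600) at 3865 ± 373 against 1546 ± 395. Of 49 starch, sugar and trehalose genes, 14 were higher and 4 lower. BAM1 (MANES_03G155800), an amylase of starch breakdown, was at 39.6 ± 10.5 against 9.42 ± 4.38, and TPS9 (MANES_05G087900) was lower, at 0.859 ± 0.493 against 6.81 ± 2.98. Of 39 gibberellin genes, 9 were higher and 0 lower. GA20ox1 (MANES_14G031200), of gibberellin synthesis, was at 26.9 ± 9.74 against 4.75 ± 5.37 (2.65 ± 0.44, adjusted p = 2.69e-05), and GA2ox8 (MANES_15G076100), of gibberellin breakdown, at 19.9 ± 3.78 against 4.09 ± 2.68. Of 34 nitrogen and phosphate genes, 10 were higher and 2 lower, with AMT1.1 (MANES_03G156400) at 223 ± 33.3 against 67.7 ± 12.4 and the nitrate transporter NRT1.7 (MANES_05G095700) at 29.9 ± 6.39 against 9.61 ± 5.01.

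Of 41 immune genes in August, 12 were lower and 2 higher. WRKY33 (MANES_02G189600) was at 5.21 ± 1.85 against 38 ± 7.12 (-2.68 ± 0.38, adjusted p = 2.5e-06), and the chitinase PR3 (MANES_11G106100) spanned 0 to 3.96 against 20.9 ± 3.66. Of 39 jasmonate genes, 8 were lower and 3 higher: JAZ8 (MANES_17G071600) was listed at 0 against 5.57 ± 2.72, and AOS (MANES_18G031800), a synthesis enzyme, was higher at 18.3 ± 7.34 against 3.27 ± 1.35. Abscisic acid genes were 13 higher and 7 lower of 46, the latter including the receptor PYL4 (MANES_09G110800) at 60.3 ± 29.6 against 363 ± 131 and CYP707A1 (MANES_10G067700), of abscisic acid breakdown, with a range of 0 to 0.627 against 16.9 ± 4.97. TEM1 (MANES_06G071700), a repressor of FT in Arabidopsis, was listed at 0 against 5.22 ± 2.19 (adjusted p = 0.000171). COL16 (MANES_14G102400), of the CONSTANS-like family, was at 14.3 ± 8.65 against 141 ± 47 (-3.31 ± 0.40, adjusted p = 1.14e-07), and the clock gene RVE8 (MANES_09G079800) was higher at 31.1 ± 4.02 against 10.1 ± 0.973.

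Heat shock genes split in August, 5 higher and 5 lower of 46. HSP17.6II (MANES_16G083600) was at 35.8 ± 13.6 against 713 ± 547 (-3.95 ± 0.45, adjusted p = 3.85e-08) and HSP21 (MANES_12G017300) at 3.71 ± 2.91 against 91 ± 97.9. HSP70-4 (MANES_10G032000) was higher, at 545 ± 71.4 against 65.8 ± 38.5 (3.20 ± 0.29, adjusted p = 2.9e-10). Of 24 cold genes 5 were higher and 0 lower, with GolS2 (MANES_08G109300) at 47.6 ± 23.2 against 7.55 ± 6. Of 38 flavonoid genes 7 were higher and 1 lower, with chalcone synthase (MANES_03G150000) at 11.1 ± 4.63 against 1.52 ± 1.68. Among the largest changes, a DnaJ chaperone (MANES_01G223300) was at 179 ± 101 against 5.99 ± 1.94 and a prolyl oligopeptidase (MANES_18G007900) at 446 ± 175 against 25.4 ± 13.8. GER3 (MANES_11G020100) was lower at 27.6 ± 9.08 against 450 ± 127, and the ethylene-response factor ERF1 (MANES_13G033200) spanned 0 to 0.569 against 20.7 ± 11.

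In August 3396 genes were called, 1497 higher and 1899 lower, and 16.9 percent of genes had fully separated libraries against 2.86 percent by chance. The list test was passed by photosynthesis (adjusted p = 1.28e-06), clock and starch (each adjusted p = 0.000966), cold and nitrogen (each adjusted p = 0.00243), immune defence (adjusted p = 0.00364), gibberellin (adjusted p = 0.0044), abscisic acid (adjusted p = 0.00596), florigen (adjusted p = 0.00886), flavonoid (adjusted p = 0.0114) and jasmonate (adjusted p = 0.0428). Every one of these lists lost its call with an estimated correlation. The adjusted p was then 0.0505 for florigen, clock, gibberellin, starch and nitrogen, 0.0527 for cold, 0.0785 for immune defence, 0.137 for flavonoid, photosynthesis and abscisic acid, and 0.397 for jasmonate. With p adjusted over the list alone, 19 photosynthesis, 24 starch, 13 nitrogen, 15 immune, 12 gibberellin, 23 abscisic acid, 14 jasmonate, 12 clock, 10 flavonoid, 8 cold and 3 florigen genes passed.

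The October pair set Bac Kan on 5 October against Hanoi on 10 October and gave the strongest contrast in heat shock genes. Of 46 tested, 37 were higher in Bac Kan and 0 lower, with a median of 3.48, or 3.75 without 13 members that a group listed at 0. HSP90.1 (MANES_06G152800) stood at 942 ± 599 against 2.83 ± 0.213 (7.49 ± 0.52, adjusted p = 9.02e-14) and HSP17.6II (MANES_16G083600) at 520 ± 272 against 3.86 ± 1.41 (6.61 ± 0.45, adjusted p = 7.61e-14). The chaperone partner BAG5 (MANES_13G007700) was at 463 ± 602 against 1.13 ± 1.4. Of 24 cold and dehydration genes, 9 were higher and 1 lower, with GolS1 (MANES_05G012000) at 241 ± 102 against 3.08 ± 1.85 and ELIP1 (MANES_15G033100) at 1751 ± 173 in Bac Kan (4.28 ± 0.32, adjusted p = 5.32e-13). Of 38 flavonoid genes, 18 were higher and 4 lower. F3H (MANES_02G104700) was at 3.5 ± 1.07 in Hanoi and higher in Bac Kan (4.68 ± 0.38, adjusted p = 5.67e-12), DFR (MANES_18G022300) at 64.8 ± 15.5 against 2.79 ± 1.76, and ANS (MANES_01G070200), the anthocyanidin synthase, at 46.1 ± 5.8 against a range of 0 to 2.89.

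Of 49 starch, sugar and trehalose genes in October, 24 were higher and 4 lower. DPE2 (MANES_08G162200), which handles maltose from starch, was at 94.2 ± 28.6 against 11.2 ± 1.93 (2.93 ± 0.18, adjusted p = 1.28e-14), BAM1 (MANES_03G155800) at 173 ± 31.2 against 22.7 ± 6.63, and the starch branching enzyme SBE2.2 (MANES_08G022400) at 126 ± 24 against 22.7 ± 7.53. Of 46 abscisic acid genes, 22 were higher and 6 lower. AHG3 (MANES_07G119400) was at 87.5 ± 18.6 against 7.95 ± 3.15 and NCED3 (MANES_03G083500) at 15.9 ± 5.01 against 0.698 ± 0.489. PYL4 (MANES_09G110800) was lower, at 10.6 ± 3.48 against 207 ± 44.7 (-4.19 ± 0.39, adjusted p = 1.47e-10). GA20ox1 (MANES_06G141200) was at 142 ± 27.7 against 22.6 ± 8.06 (2.65 ± 0.18, adjusted p = 6.11e-14). Photosynthesis genes were 5 higher and 14 lower of 44, with PSAN (MANES_12G156000) at 80.4 ± 10.9 against 344 ± 58.6 and LHCB2.1 (MANES_01G175600) at 494 ± 102 against 1866 ± 443. LHCB2.1 had been higher in Bac Kan in late May, and the F test over all 4 pairs had adjusted p = 1.09e-09. Immune genes were 1 higher and 15 lower of 41, with WRKY33 (MANES_02G189600) at 10.4 ± 5.07 against 78.7 ± 12.5.

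Most called repressors of flowering and photoperiod genes were lower in Bac Kan in October. Of 15 repressors, 6 were lower and 0 higher: TEM1 (MANES_06G071700) spanned 0 to 0.494 against 23 ± 6.48, a second TEM1 (MANES_14G098000) was at 3.65 ± 1.79 against 54 ± 12.9, and SVP (MANES_18G059200) at 54.9 ± 12.8 against 124 ± 7.98. Of 30 photoperiod genes, 11 were lower and 1 higher. COL2 (MANES_02G062700) was at 2.85 ± 1.2 against 60.1 ± 10.4 (-4.03 ± 0.40, adjusted p = 4.14e-10) and CDF2 (MANES_05G103100) at 15.6 ± 3.13 against 47.8 ± 9.67. In late May CDF2 had been higher (F test over all 4 pairs, adjusted p = 1.84e-10). Clock genes were 4 higher and 9 lower of 28, with RVE1 (MANES_01G123100) at 18.8 ± 13.4 against 96 ± 23.5 and PRR5 (MANES_01G043200) at 50 ± 9.26 against 171 ± 26.7. SPL5 (MANES_03G106900) was now higher in Bac Kan, at 21.8 ± 6.12 against 6.71 ± 1.85, and its site difference changed over the 4 pairs (F test, adjusted p = 2.56e-10). ERF1 (MANES_13G033200) spanned 0 to 3.77 against 69.1 ± 9.73, and the touch-induced wall enzyme TCH4 (MANES_14G152100) 0 to 1.26 against 32.4 ± 9.66.

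In October 5657 genes were called, 2467 higher and 3190 lower, and 27.8 percent of genes had fully separated libraries against 2.86 percent by chance. The list test was passed by heat shock (adjusted p = 6.5e-34), starch (adjusted p = 1.87e-08), flavonoid (adjusted p = 2.92e-07), abscisic acid (adjusted p = 3.36e-06), cold (adjusted p = 0.000358), photoperiod (adjusted p = 0.000825), repressors (adjusted p = 0.00533), immune defence (adjusted p = 0.00741) and photosynthesis (adjusted p = 0.011), and not by the clock list (adjusted p = 0.121). With an estimated correlation the adjusted p was 0.000414 for heat shock and starch, 0.00497 for flavonoid, 0.0196 for abscisic acid, 0.027 for cold, 0.0289 for photoperiod and 0.0352 for repressors. Immune defence (adjusted p = 0.108) and photosynthesis (adjusted p = 0.521) then lost the call. Adjusted over the list alone, 38 heat shock, 31 starch, 24 flavonoid, 32 abscisic acid, 10 cold, 12 photoperiod, 8 repressor, 21 immune and 20 photosynthesis genes passed.

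**Figure D3:**
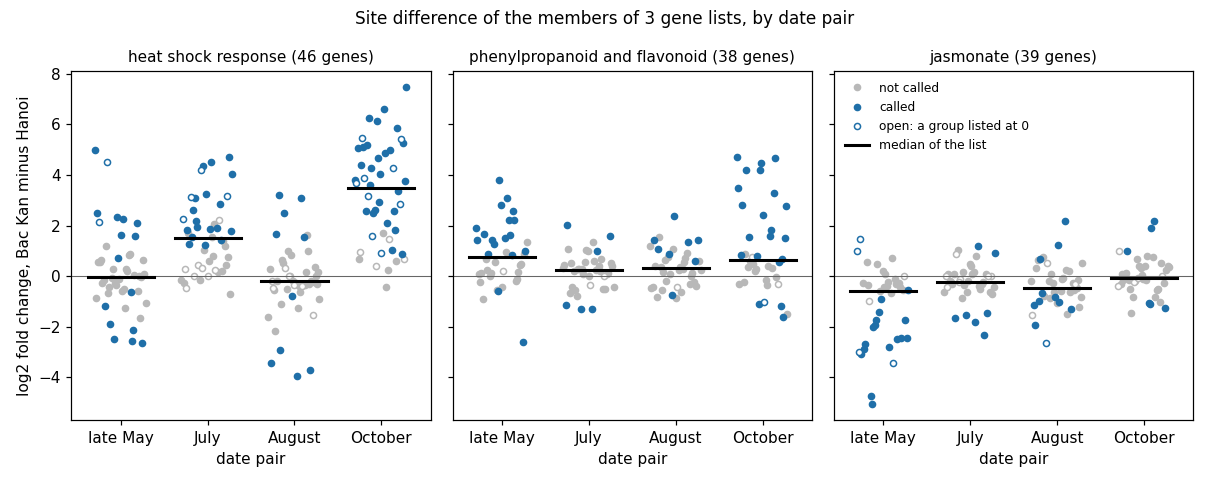
Site difference (log2 fold change, Bac Kan minus Hanoi) of every tested member of 3 lists at the 4 date pairs, 1 point per gene, filled where both groups were above 0 and open where a group was listed at 0. Of 46 heat shock genes 22 were called higher in Bac Kan in July and 37 in October, and in August 5 were higher and 5 lower.

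The mean of the 4 pairs asked which differences held on average over the season. Most called heat shock, flavonoid, cold and nitrogen genes were higher in Bac Kan, and most called immune and jasmonate genes were lower. Of 46 heat shock genes 34 were higher and 0 lower, among them HSP101 (MANES_06G085600), a disaggregating chaperone (2.33, adjusted p = 3.49e-13). October weighed heavily here: without that pair 14 were higher and 1 lower, and the median of the list was 0.464 in place of 1.36 (adjusted p = 8.55e-05). Of 38 flavonoid genes 19 were higher and 4 lower, with chalcone synthase (MANES_03G150000) at a mean difference of 2.67 (adjusted p = 8.34e-12). Of 24 cold genes 10 were higher and 1 lower, with ELIP1 (MANES_15G033100) at 2.39 (adjusted p = 2.64e-14). Of 34 nitrogen and phosphate genes 11 were higher and 1 lower. Immune genes were 2 higher and 19 lower of 41, with WRKY33 (MANES_02G189600) at -1.87, and jasmonate genes 3 higher and 17 lower of 39, with LOX2 (MANES_10G149100) at -1.66. Not every pair went this way. Heat shock genes were 10 higher and 7 lower in late May (camera adjusted p = 0.952) and 5 and 5 in August (camera adjusted p = 0.95). Cold genes were 7 higher and 7 lower in late May (camera adjusted p = 0.962). Nitrogen genes were 2 higher and 1 lower in July (camera adjusted p = 0.618), and among the pairs their list passed camera only in August (adjusted p = 0.00243). In October jasmonate genes were 3 higher and 3 lower (median -0.0769, camera adjusted p = 0.909). In July immune genes were 3 higher and 1 lower (camera adjusted p = 0.675) and flavonoid genes 3 and 3 (camera adjusted p = 0.618). Without the late May pair, 4 jasmonate genes were higher and 11 lower in the mean (camera adjusted p = 0.0445). GER3 (MANES_11G020100) at -3.13 (adjusted p = 2.98e-15), XTH9 (MANES_12G076800) at -3.19 and ERF1 (MANES_13G033200) at -2.83 were among the largest falls. RL6 (MANES_05G158300) at 3.20 (adjusted p = 1.03e-08) was the largest rise named. GA20ox1 (MANES_14G031200) was higher by 2.08 ± 0.22 (adjusted p = 1.86e-09), and TEM1 was lower in both MANES_06G071700 and MANES_14G098000 (-1.81 for the latter).

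In the mean, 5909 genes were called, 2933 higher and 2976 lower, of which 890 differed by at least 1 log2 unit. That count treats the libraries of a date as independent samples of a site. When the 11 date means were the samples, 6 genes were called, all higher in Bac Kan, with 2536 at an unadjusted p under 0.05. That fit set all 7 Bac Kan dates against all 4 Hanoi dates without pairing them, so changes over dates added to its spread. The fall in the count therefore does not measure the choice of sample alone. The 6 were GA20ox1 (MANES_14G031200, 2.26), MLP28 (MANES_17G079800, 1.96), MANES_17G038700 (1.34), MANES_05G145300 (1.77), MANES_15G159000 (1.06) and MANES_15G146800 (1.66), and were named after their values were seen. Of the genes named for the mean of the pairs, all but GA20ox1 (MANES_14G031200) lost the call in that fit, where its adjusted p was 0.0498.

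The list test over the mean was passed by heat shock (adjusted p = 6.11e-20), flavonoid (adjusted p = 2.01e-07), jasmonate (adjusted p = 3.07e-06), immune defence (adjusted p = 9e-06), cold (adjusted p = 0.000147), nitrogen (adjusted p = 0.000607), starch (adjusted p = 0.00179), abscisic acid (adjusted p = 0.00778) and photosynthesis (adjusted p = 0.0148). With an estimated correlation the adjusted p was 0.00829 for heat shock and flavonoid, 0.0118 for immune defence and nitrogen, 0.0182 for cold and 0.0356 for jasmonate and starch. Abscisic acid (adjusted p = 0.162) and photosynthesis (adjusted p = 0.469) then lost the call. Starch genes were 17 higher and 7 lower of 49, abscisic acid genes 17 and 5 of 46, and photosynthesis genes 15 and 5 of 44. With all 7 Bac Kan dates against all 4 Hanoi dates the photosynthesis list was called in the opposite direction (adjusted p = 0.0159). Without the October pair the starch and abscisic acid lists were not called (adjusted p = 0.852 and 0.711), and without the late May pair photosynthesis was not (adjusted p = 0.408). With the 11 date means as samples 7 lists were called: photosynthesis (adjusted p = 0.26), starch and abscisic acid (each adjusted p = 0.119) lost the call, and florigen gained it (adjusted p = 0.0496). When adjusted over the list alone, 36 heat shock, 24 flavonoid, 28 jasmonate, 21 immune, 12 cold, 13 nitrogen, 25 starch, 26 abscisic acid and 22 photosynthesis genes passed. By fry, heat shock (adjusted p = 7.9e-11), flavonoid (adjusted p = 2.88e-11), immune defence (adjusted p = 1.3e-09) and jasmonate (adjusted p = 1.28e-07) also moved on balance. Fry also passed some lists that camera did not call, given below.

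The other lists were not called by camera in the mean. They were florigen, with 2 of 3 genes higher (adjusted p = 0.0765), gibberellin, with 12 higher and 4 lower of 39 (adjusted p = 0.0765), and sugar starvation and senescence, with 7 and 3 of 19 (adjusted p = 0.131). Floral repressors had 1 higher and 3 lower of 15 (adjusted p = 0.182), integrators 2 and 4 of 14 (adjusted p = 0.272), and photoperiod 6 and 5 of 30 and clock 6 and 6 of 28 (each adjusted p = 0.655). By fry, florigen (adjusted p = 0.000159), gibberellin (adjusted p = 0.000105) and sugar starvation (adjusted p = 0.000197) moved up on balance. Floral repressors (adjusted p = 0.00206) and integrators (adjusted p = 0.0091) moved down by fry, and photoperiod (adjusted p = 0.293) and clock (adjusted p = 0.267) did not pass. Some of the lists that camera did not call gained its call under alternatives. Florigen did with a pseudocount of 0.1 (adjusted p = 0.0406), only the groups compared (adjusted p = 0.0279) and all dates (adjusted p = 0.0113). Gibberellin did with the deposited FPKM (adjusted p = 0.0491), median-ratio scaling (adjusted p = 0.0472), a filter of 5 (adjusted p = 0.00377), all dates (adjusted p = 0.014) and without the late May pair (adjusted p = 0.0191). Without the October pair photoperiod was called, 10 higher and 2 lower (adjusted p = 0.00517), while without the late May pair 5 were higher and 12 lower (adjusted p = 0.0512). The lists for other tissues were not called in the mean: 0 of 9 floral organ genes (adjusted p = 0.757), 1 lower of 11 proliferation genes (adjusted p = 0.655) and 1 higher of 17 secondary wall genes (adjusted p = 0.953) were called. By fry, however, the secondary wall list moved down in late May (2 of 17 lower, adjusted p = 0.000416), up in July (1 of 17 higher, adjusted p = 0.000732) and down over the Hanoi dates (3 of 17 fallen, adjusted p = 7.56e-06). The floral organ list moved up from the first to the last date in Bac Kan (adjusted p = 0.0071) and in Hanoi (adjusted p = 0.000143), and 3 of its 9 genes were called in late May. Median, mean and the camera test of a list differed in sign only where that test made no call, as for photoperiod here (median 0.0296, mean -0.0302) and for heat shock in August (median -0.205, test upward). By fry, the gibberellin list was called upward over the Hanoi dates (adjusted p = 0.0179) although its median was -0.21.

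Whether the site difference changed between the 4 pairs was asked with the interaction, which was called for 8925 genes. The B-box zinc finger gene MANES_15G081200 stood at 142 ± 80.5 in Bac Kan and 26.2 ± 6.44 in Hanoi in late May, and at 181 ± 27.4 and 2190 ± 353 in October (adjusted p = 1.93e-15). EBF1 (MANES_14G133100), an F-box protein of ethylene signalling, climbed in Hanoi from 11.5 ± 3.5 to 244 ± 31.5 while its Bac Kan means stayed between 40.4 ± 4.92 and 73.3 ± 16.3 (adjusted p = 9.76e-15). The Rossmann-fold gene MANES_08G029700 was higher in Bac Kan in late May (319 ± 43.4 against 38.5 ± 12.9) and lower in July (40.9 ± 12.6 against 139 ± 15.4), also with adjusted p = 1.93e-15. UBL5 (MANES_08G007500) was at 170 ± 7.87 against 86.7 ± 4.97 in late May and 112 ± 11.2 against 283 ± 25 in October, and ATAB2 (MANES_10G140800), needed to translate photosystem proteins, at 225 ± 24.5 against 63.7 ± 9.87 and 97.1 ± 9.29 against 178 ± 15.6. By list, the interaction was called for 35 of 46 heat shock, 35 of 44 photosynthesis, 36 of 46 abscisic acid, 37 of 49 starch and 26 of 39 jasmonate genes. Adjusted over the list alone these were 38, 36, 38, 39 and 26. Of the floral organ, proliferation and secondary wall lists, 2 of 9, 2 of 11 and 3 of 17 were called.

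The course over the 7 Bac Kan dates asked which transcripts moved as the season passed at the flowering site. It was called for 10474 genes. Most photosynthesis genes fell, and most called nitrogen and phosphate genes rose. From 31 May to 30 October, 35 of 44 photosynthesis genes fell and 1 rose. PSBR (MANES_03G082900), a photosystem subunit, went from 1098 ± 471 to 62.4 ± 10.3 (-4.05 ± 0.20, adjusted p = 5.47e-18), LHCB6 (MANES_14G167100) from 1920 ± 253 to 351 ± 56.8 (-2.45 ± 0.14, adjusted p = 4.82e-16), LHCA2 (MANES_12G011200) from 547 ± 85 to 100 ± 20.5 and PSAO (MANES_04G000900) from 583 ± 287 to 68 ± 33.4. Of 34 nitrogen and phosphate genes 17 rose and 3 fell. The phosphatase PAP17 (MANES_14G173500) went from 0.991 ± 0.683 to 30 ± 12.5 (3.88 ± 0.58, adjusted p = 2.3e-06), the phosphate sensor SPX3 (MANES_01G269100) from 4.81 ± 2.79 to 47.2 ± 5.61, and AMT1.1 (MANES_03G156400) from 59.8 ± 18.9 to 328 ± 42.2 (2.47 ± 0.24, adjusted p = 2.2e-10).

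Of 14 floral integrators in Bac Kan, 7 rose and 2 fell between these dates, and of the 3 florigen genes BFT (MANES_14G027800) and FT (MANES_13G000800) rose. SPL5 (MANES_03G106900) fell from 40.4 ± 6.78 to 10.4 ± 7.19. Clock genes were 10 risen and 1 fallen of 28, with RVE1 (MANES_02G080700) from 0.874 ± 0.143 to 30.5 ± 6.02 (4.06 ± 0.38, adjusted p = 8.56e-11). Gibberellin genes were 17 and 1 of 39, with GA2ox8 (MANES_15G076100) from 8.4 ± 4.11 to 67.8 ± 6.17. Of the floral organ list 2 of 9 rose, among them SHP1 (MANES_02G085500), from 7.91 ± 4.87 to 75.9 ± 7.91. Starch genes were 6 risen and 12 fallen of 49: BAM3 (MANES_15G171200) went from 61.8 ± 9.26 to 407 ± 19.2 (2.71 ± 0.19, adjusted p = 4.97e-14) and DPE2 (MANES_08G162200) from 142 ± 6.79 to 28.9 ± 9.21. Heat shock genes were 4 risen and 15 fallen of 46, with HSP21 (MANES_01G042200) from 241 ± 83 to 3.32 ± 2.55. That count compares only the first and last dates and does not show a steady fall between them. In the Bac Kan groups of the pairs above, the mean of HSP90.1 (MANES_06G152800) was higher in October than in July. That of HSP17.6II (MANES_16G083600) was higher in October than in August. Among the largest changes, the borate transporter BOR4 (MANES_11G048700) went from 4.2 ± 1.69 to 210 ± 29.7, CYP82C4 (MANES_12G048600) from 6.7 ± 2.12 to 244 ± 57.3 and MLP423 (MANES_05G089800) from 2641 ± 644 to 98.1 ± 36.4. LOX2 (MANES_10G148800) rose to 224 ± 17.9 from 54.4 ± 9.62, and C4H (MANES_18G126900), of phenylpropanoid synthesis, to 292 ± 31.3 from 77.7 ± 28.4.

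Between the first and last Bac Kan dates 6060 genes were called, 3766 risen and 2294 fallen, and 25 percent of genes had fully separated libraries against 2.86 percent by chance. The share of risen genes depended on scaling, at 62.1 percent with a common total, 52.4 percent with the deposited FPKM and 48.9 percent with median-ratio scaling. The median of all genes moved from 0.0995 to -0.00516 between the first and the last of these scalings, and in Hanoi from 0.133 to 0.0115. The list test was passed by photosynthesis (adjusted p = 7.39e-37), nitrogen (adjusted p = 0.000251), heat shock (adjusted p = 0.00181), clock (adjusted p = 0.0061), gibberellin (adjusted p = 0.00631), starch (adjusted p = 0.00863), florigen (adjusted p = 0.0164) and integrators (adjusted p = 0.0478). With an estimated correlation photosynthesis (adjusted p = 0.00118) and nitrogen (adjusted p = 0.0076) kept the call. The adjusted p was then 0.323 for heat shock, 0.079 for clock and starch, 0.0782 for gibberellin and florigen and 0.103 for integrators. With p adjusted over the list alone, 36 photosynthesis, 23 nitrogen, 20 heat shock, 13 clock, 19 gibberellin, 20 starch, 2 florigen and 9 integrator genes passed.

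Over all 7 Bac Kan dates, the smallest p belonged to a pfkB-like sugar kinase (MANES_01G116600), which went from 497 ± 66.3 on 31 May to 87.8 ± 9.47 on 30 October (adjusted p = 3.34e-20). CYP714A1 (MANES_18G122800), of a family that inactivates gibberellins, dipped from 338 ± 63.8 on 31 May to 16.7 ± 3.24 on 26 July and stood at 377 ± 22.7 on 5 October (adjusted p = 9.37e-18). A chitinase (MANES_11G128300) rose from 186 ± 11.9 on 26 July to 1283 ± 170 on 5 October (adjusted p = 9.04e-19). By list, 40 of 44 photosynthesis, 25 of 28 clock, 24 of 30 photoperiod, 30 of 39 gibberellin and 38 of 46 heat shock genes changed. Adjusted over the list alone, 40, 25, 27, 32 and 42 did.

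The course over the 4 Hanoi dates asked the same at the non-flowering site, and 11793 genes were called. Most called photoperiod and clock genes rose there, and most called heat shock, starch, jasmonate and abscisic acid genes fell. The clock, jasmonate and abscisic acid lists lost their call with an estimated correlation. The last against the first Hanoi date uses the libraries of 24 May and 10 October, which also stand in the late May and October pairs. This contrast is therefore not independent of those site differences. From 24 May to 10 October, 21 of 30 photoperiod genes rose and 0 fell. COL2 (MANES_02G062700) reached 60.1 ± 10.4 from a range of 0 to 1.86, and CDF3 (MANES_06G091600) 61.1 ± 6.28 from 4.71 ± 4.74 (3.85 ± 0.37, adjusted p = 9.01e-11). Of 28 clock genes 12 rose and 4 fell: LHY went from 5.39 ± 2.73 to 94.6 ± 12.6 in MANES_01G239000 and from 20.1 ± 8.14 to 267 ± 15.8 in MANES_05G015600, and PRR5 (MANES_05G016200) from 9.45 ± 3.77 to 98.1 ± 15 (3.32 ± 0.25, adjusted p = 1.71e-13). Heat shock genes fell in 30 of 46 cases and rose in 0. HSP90.1 (MANES_06G152800) went from 238 ± 80 to 2.83 ± 0.213 (-5.90 ± 0.52, adjusted p = 8.72e-12) and HSFA6B (MANES_01G204200) from 78.3 ± 27.8 to 2.51 ± 1.41. Of 49 starch genes 27 fell and 4 rose, with DPE2 (MANES_08G162200) from 195 ± 7.67 to 11.2 ± 1.93 (-4.02 ± 0.18, adjusted p = 1.95e-19) and SBE2.2 (MANES_08G022400) from 186 ± 33.3 to 22.7 ± 7.53.

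BFT (MANES_14G027800) rose in Hanoi from 0 in the 4 libraries of 24 May to 183 ± 54. SPL5 (MANES_03G106900) had the largest fall among the genes named, from 809 ± 178 to 6.71 ± 1.85 (-6.72 ± 0.35, adjusted p = 1.13e-17). Floral repressors were 7 risen and 2 fallen of 15, with TEM1 (MANES_06G071700) from a range of 0 to 1.89 to 23 ± 6.48. Abscisic acid genes were 9 risen and 22 fallen of 46: RD22 (MANES_06G160100) went from 218 ± 63.6 to 2.53 ± 1.74 (-6.05 ± 0.36, adjusted p = 2.56e-16), AHG3 (MANES_07G119400) from 198 ± 52 to 7.95 ± 3.15, and the receptor PYL4 (MANES_09G110800) from 5.56 ± 1.59 to 207 ± 44.7. Jasmonate genes were 6 and 19 of 39, with JAZ8 (MANES_17G071600) down to a range of 0 to 1.8 from 67 ± 36.1. The chitinase PR3 (MANES_S012500) fell from 717 ± 126 to 25.3 ± 9.1, and NRT1.7 (MANES_05G095700) to a range of 0 to 0.454 from 32.9 ± 16. Rubisco activase (MANES_10G027600) rose from 1138 ± 555 to 6348 ± 404, and kaurene synthase (MANES_16G065800), of gibberellin synthesis, from 10.7 ± 3.59 to 181 ± 13.7 (4.02 ± 0.26, adjusted p = 3.41e-15). Of 9 floral organ genes 4 rose, with SHP1 (MANES_02G085500) at 39.2 ± 4.44 from a range of 0 to 7.44.

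Between the first and last Hanoi dates 9952 genes were called, 5924 risen and 4028 fallen (59.5 percent risen, or 51.2 with median-ratio scaling), and 33.9 percent of genes had fully separated libraries against 2.86 percent by chance. The list test was passed by heat shock (adjusted p = 4.49e-13), starch (adjusted p = 7.59e-09), photoperiod (adjusted p = 7.32e-08), jasmonate (adjusted p = 0.000516), abscisic acid (adjusted p = 0.00126) and clock (adjusted p = 0.0232). With an estimated correlation the adjusted p was 0.0365 for heat shock, 0.000593 for starch and 0.00124 for photoperiod, while jasmonate and clock (each adjusted p = 0.14) and abscisic acid (adjusted p = 0.132) lost the call. When adjusted over the list alone, 30 heat shock, 31 starch, 21 photoperiod, 25 jasmonate, 32 abscisic acid and 17 clock genes passed.

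Over all 4 Hanoi dates, the smallest p belonged to an HSP20-like gene (MANES_09G099300), which went from 1420 ± 133 to 42.1 ± 9.66, and to the B-box gene MANES_15G081200, which rose from 26.2 ± 6.44 to 2190 ± 353 (each adjusted p = 1.08e-21). The ABC transporter ABCG40 (MANES_04G105800) rose from 2.62 ± 1.03 to 77.3 ± 9.5 (adjusted p = 3.08e-17). By list, 40 of 44 photosynthesis, 40 of 46 abscisic acid, 40 of 49 starch and 23 of 30 photoperiod genes changed. With p adjusted over the list alone, 41, 40, 43 and 23 did.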

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

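The tests of family reads, scaling and sampling hour were chosen only after the result was seen, while the depth test and the splits were set beforehand. A library was marked when the gap to its nearest neighbour took up most of the range of its group, and a gene when its site difference changed between the 4 pairs. The first rule marks about 1 in 20 groups by chance, and it marked 20 of 220 here.

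Among florigen relatives, FT MANES_13G000800 was marked for library 2 of Hanoi 10 October at 1.21 with the other 3 at 0, and for library 3 of Bac Kan 15 August at 10.7 with the others between 5.4 and 5.87. BFT MANES_14G027800 was marked for library 1 of Hanoi 13 July at 0.524 with the others at 0. AP1 MANES_01G103200 was marked for library 1 of Hanoi 24 May at 2 with the others at 0, and for library 1 of Hanoi 10 October at 0 with the others between 1.87 and 1.94. FUL MANES_02G059300 was marked for library 1 of Bac Kan 29 June at 21.5 (others 18.9 to 19.2) and library 4 of Bac Kan 26 July at 22.2 (others 11.9 to 13.3). FUL MANES_14G088500 was marked for library 3 of Bac Kan 5 October at 246 (others 280 to 286).

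Among clock genes, LHY MANES_01G239000 was marked for library 4 of Bac Kan 30 October at 98.8 (others 67 to 70.1) and LHY MANES_05G015600 for library 1 of Bac Kan 26 July at 73.9 (others 45.3 to 45.7). TOC1 MANES_06G089800 was marked for library 3 of Bac Kan 11 September at 6.82 (others 11 to 11.7). TOC1 MANES_14G081500 was marked for library 3 of Hanoi 10 October at 11 (others 6.62 to 7.25) and library 3 of Bac Kan 5 October at 22.3 (others 13.9 to 15).

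Of the measures of whole libraries, library 4 of Hanoi 10 October was marked for 19406 genes at 1 or more (others 19231 to 19248). By median correlation with its own group, library 1 of Hanoi 24 May was marked low at 0.8651 (others 0.8802 to 0.8808), as were library 1 of Bac Kan 29 June at 0.9332 (others 0.9375 to 0.9378) and library 2 of Bac Kan 26 July at 0.9259 (others 0.9279 to 0.928). Marked high were library 4 of Hanoi 13 July at 0.9234 (others 0.9128 to 0.9146), library 2 of Hanoi 7 August at 0.9388 (others 0.928 to 0.929) and library 4 of Bac Kan 30 October at 0.9256 (others 0.9225 to 0.923). No library was left out of the reported values for these marks.

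The site difference changed between the pairs for 8925 genes, and for 8 of the 16 tested genes that were named in every case. Its range over the 4 pairs in log2 units was 2.82 for FT MANES_12G001600 (adjusted p = 0.0421), 3.52 for BFT MANES_14G027800 (adjusted p = 0.000294), 2.11 for FUL MANES_02G059300 (adjusted p = 1.14e-05), 3.33 for FUL MANES_14G088500 (adjusted p = 0.0214) and 1.64 for SOC1 MANES_05G041900 (adjusted p = 0.000303). It was 2.69 for CO MANES_01G024100 (adjusted p = 0.0124), 2.38 for LHY MANES_01G239000 (adjusted p = 2.24e-05) and 3.01 for LHY MANES_05G015600 (adjusted p = 3.54e-08). The 2.82 and the 2.69 rest on Hanoi groups listed at 0 in all 4 libraries, so their size is set by the pseudocount and measures no fold change.

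FT homologues were listed at or near 0 in Hanoi, which too little depth there could produce. Of genes with a mean of 3 to 10 in Bac Kan, 1.14 percent were at 0 in all 4 Hanoi libraries in October and 0.879 percent in August, which argues against too little depth. Reads given to another family member were looked for in the sum of the 10 members, which reached at most 1.78 in the 12 Hanoi libraries of May to August, against 5.01 as the lowest Bac Kan group mean of MANES_13G000800 from June on, a group with 2 of 4 libraries at 0. That argues against this cause for those months, and leaves October open because BFT was high then. A different hour of sampling stays open, with 8 clock genes called in August, as does a difference of site, field or flowering state, which was not tested.

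Heat shock genes were higher in Bac Kan in July and October but not in August, and scaling of the libraries or the hour of sampling might produce this. With median-ratio scaling the October median of the list was 3.13, against 3.48 with a common total, which argues against scaling. A different hour of sampling stays open, with 3 clock genes called in July. Weather on the days of sampling was not tested and stays open too.

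In October LHY was lower and TOC1 higher in Bac Kan, which an earlier hour of sampling in Hanoi could produce. Over the other clock genes the median difference was -0.772 for 11 morning genes and -0.136 for 10 evening genes. The gap of -0.636 had the direction of an earlier hour of sampling, but the rise of evening genes that it called for was not seen, so this stays open. In the August pair the gap had the other sign, at 0.746, with medians of 0.717 for morning and -0.0285 for evening genes. A difference in the clock between the sites was not tested and stays open.

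Chance was tested by splitting the libraries in other ways, with the real split counted among the splits. In late May 1 of 35 splits called as many genes as the real 6714, in July 1 of 35 as many as 2068, in August 1 of 35 as many as 3396 and in October 1 of 35 as many as 5657. The highest other counts were 1645, 22, 583 and 34. For the mean of the pairs it was 1 of 100 for 5909 genes (highest other 1864), and for the interaction 1 of 100 for 8925 (highest other 1281). Over dates it was 1 of 100 for 10474 genes in Bac Kan (highest other 954) and 1 of 100 for 11793 in Hanoi (highest other 7737). Between the first and last dates it was 1 of 35 for 6060 genes in Bac Kan (highest other 890) and 1 of 35 for 9952 in Hanoi (highest other 1834). For the 9 gene lists it was 4 of 100, with a highest other count of 10 and a median of 3 lists in the other splits. The counts for the pairs, their mean and the changes over dates met the rule of fewer than 5 percent, though 1 of 35 is the lowest share that 35 splits can give. Chance in how single libraries fell into groups is therefore an unlikely source of these counts. The gene lists met the rule only narrowly, with a highest other count above the real 9, so chance is not excluded for them. For the interaction the splits moved libraries between the dates of a site. They removed changes over dates along with any interaction, so they cannot decide on chance for the interaction itself. The splits do not test chance between dates: with the 11 date means as samples 6 genes were called in the mean, so that stays open there. Some other splits called many genes too, and whether they carried part of the real difference or further structure was not tested.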

How the results depend on the processing

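The alternatives without the late May or the October pair, and with only the most abundant transcript of each gene, were chosen after seeing the data. Where a result moved with them or with one set beforehand, the cause was not tested, unless the construction shows it. No paired analysis was possible because the columns carry no replicate number, so libraries of different groups cannot be matched. The replicate numbers of the labels and the site given in the characteristics were for the same reason not run as alternatives. Each site was 1 field, and no alternative separates site from field, day or hour.

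Some settings are stricter by construction and lowered the counts of called genes. With at least 1 log2 unit asked, 3974 genes were called in late May, 1066 in July, 1929 in August, 3301 in October, 890 in the mean of the pairs and 3465 from the first to the last Bac Kan date. With adjusted p below 0.01 these were 4376, 1040, 2021, 3642, 3810 and 4033. With the 11 date means as samples, a fit that also dropped the date pairing, 6 were called in the mean. Fitting only the groups compared went both ways, with 3458 genes in late May and 1201 in July but 5981 in October and 10847 over the Bac Kan dates. Bac Kan 29 June in place of 26 July gave 3387 genes for July.

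Directions turned in few places. With the 11 date means as samples the mean difference of MANES_03G082900 was -0.089, and with all 7 Bac Kan dates against all 4 Hanoi dates it was the same -0.089, both without a call, while the photosynthesis list was then called in the opposite direction (adjusted p = 0.0159). Bac Kan 29 June in place of 26 July turned the July difference into a call in the other direction for MANES_06G141200 (0.73, adjusted p = 0.0033), MANES_17G066700 (-0.97, adjusted p = 0.0326) and MANES_05G041900 (-1.18, adjusted p = 0.000166). It changed the sign without a call for MANES_01G012000 (-0.21), MANES_09G182500 (0.22), MANES_01G264100 (-0.028), MANES_08G022500 (0.17), MANES_02G189600 (0.9999), MANES_10G011800 (0.054) and MANES_06G160100 (-0.22). Without the late May pair the mean difference of MANES_02G059300 was -0.48, a call (adjusted p = 0.00918). Without the October pair that of MANES_02G062700 was 0.40 and that of MANES_01G239000 was 0.018, both without a call. With only the most abundant transcript, the change between the first and last Bac Kan dates was -1.55 for MANES_05G041900 and -0.71 for MANES_18G095000, neither of them a call (adjusted p = 0.492 and 0.766).

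Each of the 44 libraries was left out in turn. The counts then lay between 5791 and 6753 in late May, 1541 and 2225 in July, 2679 and 3563 in August, 4762 and 5848 in October, and 5573 and 6076 in the mean. They lay between 8357 and 8984 for the interaction, 9883 and 10902 over the Bac Kan dates, 10980 and 11831 over the Hanoi dates, 5082 and 6282 from the first to the last Bac Kan date, 9067 and 10002 from the first to the last Hanoi date, and 8 and 10 for gene lists.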
